A study of Ericerus pela with 2 samples.

How the data were processed

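The series holds 2 RNA libraries from males of Ericerus pela, the Chinese white wax scale insect, 1 from prepupae and 1 from pupae. Per the labels' protocols, whole bodies were used and libraries were made with standard Illumina procedures. The submitters' design note names the retina instead, and the files alone do not settle which of these holds. Both samples carry an age of 90 with no unit. The design note states that there were no replicates.

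Each deposited table lists unigenes, the assembled transcript fragments of a species without a genome used here. Per the file headers, a table gives for each unigene the count of uniquely assigned reads, its length in bases, the percent of its length covered by reads, an RPKM value (reads scaled to unigene length and to the library total), Gene Ontology terms and the best protein database match. The deposited counts were whole numbers and summed to the totals in the headers, 2182108 reads in prepupae and 1840877 in pupae. The deposited RPKM equalled the value recomputed from the reads, the length and the total for 100% of values in each library, within a relative tolerance of 1e-06. Unigenes with 1 read had a median of 49 bases covered, which gave the read length; the deposited percent of length covered was used only for this. The assembler, aligner, database versions and read filters are not given in the sources used here. Since reads assigned to more than 1 unigene were not counted, per the file headers, near-identical copies of a gene may have lost reads in both libraries.

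The tables were joined on the unigene identifier. A unigene absent from a table was given 0 reads, as the tables list only unigenes with at least 1 read. The protein name was taken from the database match, and gene-model numbers, hypothetical and uncharacterised proteins were not counted as names; the gene-model formats were completed after the first results had been seen. Several unigenes often match 1 protein, as fragments of a transcript or as related genes, so a count of unigenes is not a count of genes.

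The measure of change was the log2 ratio of RPKM in pupae to RPKM in prepupae, with a pseudocount of 1 added to each, over unigenes with a mean RPKM of at least 1. This scale understates the change of low unigenes. With 1 library per stage no test across samples and no p-value can be given. A unigene was called higher or lower in pupae where it differed at least 2-fold on this scale, a fixed rule of size. Folds printed for named unigenes are ratios of reads scaled to the library totals (RPM), with the exact (Clopper-Pearson) conditional binomial 95% interval. Intervals and floors cover counting error only, not the spread between animals. Against 0 reads the fold was computed from a floor of 3 counts in that library, which is 1.37 RPM in prepupae and 1.63 in pupae, and is given as a lower bound. This bound takes the count of the other library as exact. It is less strict than the counting interval, whose lower end for tropomyosin 2 was 65.6 against a bound of 81.4. The number of calls that counting error alone would give was estimated from 20 seeded binomial redistributions of each unigene's reads between the libraries.

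A total of 32 gene lists had been fixed as keyword patterns before the data were examined, and they were matched to the database match of each unigene. The median log2 ratio of a list was placed as a percentile among the medians of 10000 random lists of the same size, drawn with replacement from filtered unigenes in the same 20 classes of mean expression. Lists at or above percentile 97.5 or at or below 2.5 are called extreme; the percentile describes these libraries and is not a test across samples. The interval of a list's median is the distribution-free interval over its members. Keyword patterns also caught proteins that do not belong to a list; a version without them was added after the data had been seen. Gene Ontology terms with at least 25 unigenes were treated in the same way, with 2000 random lists, 10 expression classes and a background of unigenes that had a term of the same branch.

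The genes named in the text follow a rule that had also been fixed in advance. Among unigenes with a protein name, reads in both libraries and at least 50 reads in total, the 12 with the largest increase and the 12 with the largest decrease could be named, 1 per protein name, together with up to 4 members of each list. A further 14 genes of hormone signalling, chitin, lipid, sex and yolk were looked up whatever their change, and the 5 most abundant unigenes of each library were included. Tyrosine hydroxylase, tropomyosin 2, Edg-78E, cuticular protein 15, the prophenoloxidases, PCNA, troponin C, rhodopsin 1/6, the odorant receptors, phosphoenolpyruvate carboxykinase, glycogen synthase, the monocarboxylate transporters, the aminoacyl-tRNA synthetase and splicing factor 8 were chosen after their values had been seen, as were all sums over protein families and the single doublesex, epoxide hydrolase, juvenile hormone esterase and FTZ-F1 unigenes given beside their sums.

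The calculations were tested on simulated data. Reads were drawn for the 113976 filtered unigenes from their pooled means, with 200 unigenes changed by known folds. The size rule recovered 100% of the 50 unigenes at each of 4-fold and 8-fold higher or lower, and called 0.454% of the 22468 unchanged unigenes with at least 50 reads. The counting interval held the true fold for 95.8% of these unchanged unigenes. Of 200 unchanged lists of 60 members, 5.5% fell at or beyond percentiles 2.5 and 97.5. Such a share is largely set by construction, since reads were simulated for each unigene separately. It checks the calculation only. It does not show how often real lists would be extreme, as their members can be fragments of a shared transcript or related genes that change together.

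The alternatives were pseudocounts of 0.1 and 5, centring the log2 ratios on their median, scaling by TMM (trimmed mean of M-values, edgeR 4.0.16 in R 4.3.3), no expression filter, a mean of at least 5, 1 unigene per annotation text, unigenes of at least 500 bases, a 4-fold threshold, counting intervals beyond 2-fold, random lists matched on length, and thinning of the deeper library. Scaling without the 100 most abundant unigenes of either library, a background of annotated unigenes and the lists without off-target members were added after the data had been seen. No count test was run, since edgeR needs replicates to estimate a spread. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.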

Results

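Scale insects are sexually dimorphic. Females stay wingless and larva-like, while males pass through prepupal and pupal stages to a winged adult that does not feed. The series is about the developmental programmes and transcription factors behind this difference, and the males analysed here show the step from prepupa to pupa. The prepupal library had unique reads on 106752 unigenes, and the somewhat shallower pupal library on 94524. Together they covered 120710 unigenes, of which 80566 had reads in both, 26186 in prepupae alone and 13958 in pupae alone. Most of the unshared unigenes were shallow, with medians of 2 reads and 1 read. The unigenes were short, with a median of 254 bases, and 27626 of them (22.9%) had a database match, most often in the pea aphid Acyrthosiphon pisum (6374 unigenes). There were no replicates, so each difference below compares 1 library with 1 library and has no replicate check.

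Reads were spread more evenly over unigenes in prepupae than in pupae. The 100 most abundant unigenes took 2.22% of prepupal reads (exact 95% binomial interval 2.20 to 2.24) and 6.89% of pupal reads (6.85 to 6.92). By RPKM the shares were 2.72% and 7.73%, and those of the top 10 were 0.636% and 1.80%. The most abundant prepupal unigene by RPKM was a heat shock protein 70 (4568 RPKM), and a small heat shock protein followed (2676 RPKM); the other 3 of its top 5 had no annotation. None of the pupal top 5 had an annotation, and the first of them held 8513 RPKM in pupae and 3.01 in prepupae. Across the 113976 filtered unigenes, Spearman's rho between the libraries was 0.566, a description across unigenes, which are not independent replicates.

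**Figure D1:**
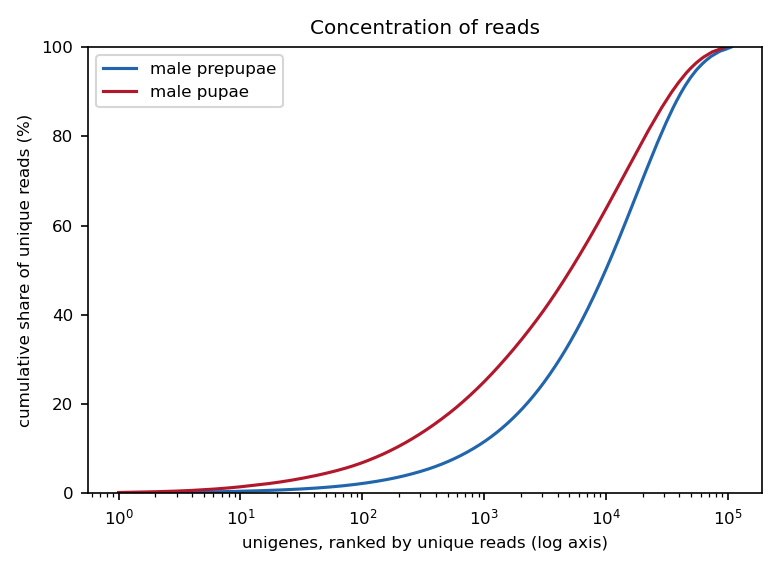
Cumulative share of unique reads (percent) against the rank of unigenes by reads (log axis) in the male prepupal and male pupal libraries. The top 100 unigenes held 2.22% of prepupal and 6.89% of pupal reads.

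By the rule of size, 26264 unigenes were at least 2-fold higher in pupae and 44893 were lower. Counting error alone would give 15811 and 19107 such unigenes, because most carry few reads. Among the 22668 unigenes with at least 50 reads, 4485 were higher and 8217 lower, against 30 and 42 from counting error. The median log2 ratio of all filtered unigenes was −0.49 (0.712-fold), so calls leaned towards lower values in pupae. Of all calls, 63.1% were lower as deposited, 54.2% with TMM scaling and 51.1% after centring on the median. Medians of gene lists are therefore given below relative to this overall shift, while counts of members and folds of named unigenes are on the deposited scale. A relative median is not the distance to random lists matched on expression, which only the percentile uses. Raw medians of those random lists were −0.04 for muscle, −0.08 for respiration, −0.23 for glycolysis and the citric acid cycle, and −0.53 for sperm and cilia. After centring, the calls turned from mostly lower to mostly higher in the lists for chitin, glycolysis and the citric acid cycle, lipid breakdown, respiration, histones, homeobox genes, eyes and mobile elements.

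Several eye and nervous system transcripts were higher in pupae. Proteins of phototransduction included the long-wavelength opsin, the visual pigment, at 2 reads in prepupae and 133 in pupae (78.8-fold, 95% counting interval 21.4 to 658). An Arr2-like arrestin, which shuts off activated rhodopsin, was 78.7-fold higher (33.4 to 244), and ninaC, a photoreceptor myosin kinase, 93.5-fold higher (47.2 to 218). The 6 opsin unigenes, 5 of them higher, together held 11 reads in prepupae and 384 in pupae (41.4-fold, 22.9 to 83.6), and a rhodopsin 1/6-like unigene went from 0 to 70 reads, at least 27.7-fold higher. The retinal homeobox protein Rx, a regulator of eye development, was 4.90-fold higher (3.05 to 8.21).

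The list of eye and phototransduction genes had 32 of 118 members higher and 41 lower, a median 0.60 above the overall median and percentile 99.53. Many members were off-target keyword matches such as retinoblastoma-binding proteins; without these, 21 of 49 members were higher and 3 lower. On the full list, centring gave 42 higher and 28 lower. Its raw median was 0.11, and −0.15 among members of at least 500 bases. Neuronal and synaptic genes had 97 of 241 members higher 31 lower and 113 neither, with a relative median of 1.12 and percentile 100. Among them, a synaptic vesicle protein was 14.8-fold higher (9.39 to 24.7), synaptotagmin I, the calcium sensor of transmitter release, 14.9-fold (6.07 to 47.6), and complexin, which controls vesicle fusion, 10.9-fold (5.98 to 21.7).

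Odour and taste genes had 11 of 21 members higher and 6 lower (relative median 1.55, percentile 99.90). All 6 odorant and gustatory receptor unigenes were higher, with 65 and 244 reads in sum. These include the trehalose-named gustatory receptors, of which gustatory receptor trehalose 1 had 44 and 78 reads (2.10-fold, 1.43 to 3.11). Another of the 6, similar to the odorant receptor Or7, had 1 read in prepupae and 29 in pupae (34.4-fold, 5.70 to 1404). Sensory neuron membrane protein 1, which takes part in pheromone detection, was 43.1-fold higher (18.2 to 134), and an odorant-binding protein was 1.71-fold lower (1.12 to 2.66), short of the rule. This list rests on few unigenes. Without the trehalose-named gustatory receptors its percentile was 90.8 (97.7 against annotated unigenes), and its 2 members of at least 500 bases had a median of −2.17.

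Structural proteins of the cuticle were among the clearest increases. Of 17 members, 12 were higher and 1 was lower (relative median 2.68, percentile 100). A cuticular protein of the RR-3 family had 33 reads in prepupae and 680 in pupae, 24.4-fold higher (17.2 to 35.8), and cuticular protein 47Ef was 16.3-fold higher (6.02 to 61.9). The pupal cuticle protein Edg-78E had 0 and 110 reads, at least 43.5-fold higher, and cuticular protein 15 had 0 and 122, at least 48.2-fold higher.

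Enzymes that tan and colour the cuticle split into opposite directions. Aspartate 1-decarboxylase, which supplies beta-alanine, was 57.6-fold higher in pupae (36.2 to 97.7), and Ebony, which joins beta-alanine to dopamine, 51.7-fold (21.8 to 161). Laccase 2, the oxidase that hardens cuticle, was 54.8-fold higher (29.5 to 115). Tyrosine hydroxylase, the entry enzyme of dopamine synthesis, rested on 2 unigenes with 8 reads in prepupae and 803 in pupae (119-fold, 60.1 to 277). Prophenoloxidases, precursors of the melanin-forming enzyme of the haemolymph, went the other way. Of their 16 unigenes 14 were lower and none was higher, and their summed reads were 957 and 70, 11.5-fold lower (9.04 to 14.9). The whole tanning list had 19 of 56 members higher and 27 lower (relative median −0.23, percentile 9.56), and its summed reads, scaled to the library totals, were 3.78-fold higher (3.59 to 3.99), opposite in sign to the median. Without prophenoloxidases 19 of 40 were higher and 13 lower. The list turned with the choice of unigenes: the percentile was 54.1 at a mean of at least 5, and the 16 members of at least 500 bases had a raw median of 1.22 at percentile 99.7.

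Genes of chitin metabolism had 7 of 48 members higher and 10 lower (relative median 0.29, percentile 85.19); summed reads were 1.18-fold higher (1.09 to 1.28) against a raw median of −0.20. A chitinase was 15.7-fold higher (5.79 to 59.8) and chitin deacetylase 5 was 7.05-fold higher (4.25 to 12.3). The 11 chitin synthase unigenes held 176 and 97 reads in sum (0.653-fold, 0.505 to 0.842), near the overall shift. Among the 16 list members of at least 500 bases the raw median was 0.38 and the percentile 98.4.

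Many muscle transcripts were higher in pupae. Of 143 members, 61 were higher, 8 lower and 74 neither (relative median 1.21, percentile 99.99). Among the 34 of at least 500 bases, 16 were higher and 3 lower. Their relative median was 1.38 and the percentile 93.8. The sarcoplasmic calcium pump, which returns calcium to the store after contraction, had 168 and 1053 reads, 7.43-fold higher (6.31 to 8.80). Muscle myosin heavy chain was 16.4-fold higher (8.06 to 39.04) and troponin C 4.74-fold (2.55 to 9.49). Tropomyosin 2, a regulator of the thin filament, had 0 and 206 reads, at least 81.4-fold higher. The 55 unigenes of titin, an elastic scaffold of the sarcomere, held 6768 and 11696 reads, 2.05-fold higher in sum (1.99 to 2.11), and 18 of them were called higher and none lower.

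Some enzymes of energy metabolism were far higher in pupae while their full lists were not extreme. Citrate synthase, the entry enzyme of the citric acid cycle, had 69 and 1701 reads, 29.2-fold higher (23.0 to 37.7). Glycerol-3-phosphate dehydrogenase, which carries reducing power to flight muscle mitochondria, was 11.5-fold higher (9.83 to 13.6), and aconitase 11.2-fold (9.05 to 14.1). Glycolysis and citric acid cycle genes had 24 of 109 members higher and 43 lower (relative median 0.03, percentile 15.1), with summed reads 1.74-fold higher (1.68 to 1.79) although the raw median was −0.46. Fatty acid breakdown enzymes included 3-ketoacyl-CoA thiolase, 22.4-fold higher (15.9 to 32.4), and acyl-CoA dehydrogenase, 19.0-fold (14.4 to 25.4). The list of lipid breakdown and storage had 25 of 111 higher and 41 lower (relative median 0.06, percentile 53.68), with summed reads 1.75-fold higher (1.69 to 1.81) against a raw median of −0.43. Without phospholipid-related matches, 21 of 72 were higher and 21 lower, at percentile 95.6, or 99.7 against annotated unigenes. Respiratory chain genes had 5 of 46 higher and 7 lower (relative median 0.62, percentile 71.37), with NADH-ubiquinone oxidoreductase flavoprotein 1 at 2.85-fold higher (2.31 to 3.53).

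Most unigenes for fatty acid and wax ester synthesis were lower in pupae, chiefly those of fatty acid synthase. Wax is secreted by male nymphs of this species, before the stages compared here. Of 130 members, 90 were lower and 24 higher (relative median −2.22, percentile 0). Fatty acid synthase matched 61 filtered unigenes, of which 53 were lower and 7 higher, and their reads summed to 3522 in prepupae and 411 in pupae, 7.23-fold lower (6.53 to 8.03). The summed reads of the whole list were only 0.915-fold (0.882 to 0.949). Without fatty acid synthase, 37 of 69 members were lower and 17 higher, while their summed reads were 1.79-fold higher (1.71 to 1.87), opposite in sign to their raw median of −1.17. Long-chain-fatty-acid CoA ligase 1, which activates fatty acids, was 36.9-fold higher (16.7 to 102). Diacylglycerol O-acyltransferase, which completes triglycerides, had 284 and 3 reads, 79.9-fold lower (27.1 to 390). A related unigene went the other way. It was named 2-acylglycerol O-acyltransferase 2 and also diacylglycerol acyltransferase 2-like, and had 12 and 194 reads (19.2-fold higher, 10.7 to 37.7). Fatty acyl-CoA reductase, which makes the alcohols of wax esters, did not move as 1 family. Its most abundant unigene, named fatty acyl-CoA reductase 1, was 17.5-fold lower (8.27 to 44.2), fatty acyl-CoA reductase 2 was 27.0-fold higher (11.2 to 84.8), and the 6 unigenes together held 312 and 293 reads.

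**Figure D2:**
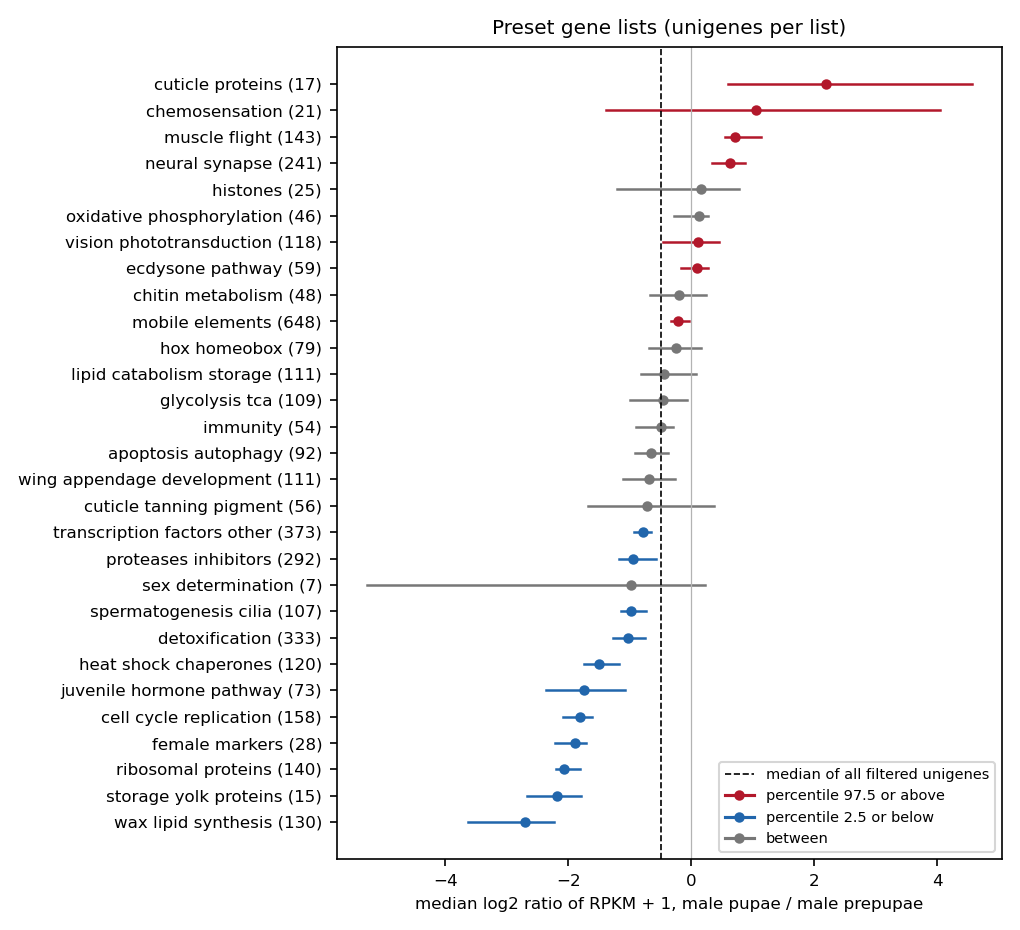
Median log2 ratio of RPKM + 1 (male pupae over male prepupae) of each preset list with the interval over its members, the number of unigenes in parentheses and the median of all filtered unigenes (−0.49) as a dashed line. Cuticle proteins lie highest (2.19) and wax and lipid synthesis lowest (−2.71).

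Most cell cycle and ribosomal protein unigenes were lower in pupae. Of 158 cell cycle and replication genes, 116 were lower and 2 higher (relative median −1.32, percentile 0). Cell division cycle 20, which triggers the exit from mitosis, had 101 and 2 reads, 42.6-fold lower (11.5 to 357), cyclin B was 77.6-fold lower (13.6 to 3098) from 92 reads to 1, and PCNA, the replication clamp, 6.54-fold lower (4.09 to 11.0). Ribosomal proteins had 103 of 140 members lower and 4 higher (relative median −1.58, percentile 0), with ribosomal protein L32 at 75 and 2 reads, 31.6-fold lower (8.46 to 266). The size of this median depends on the pseudocount, with a relative median of −0.55 and 61 lower at a pseudocount of 5 and −2.32 at 0.1, and 56 members had 0 reads in 1 library. All 166 ribosomal protein unigenes, low ones included, held 0.353% and 0.104% of reads, so the decrease rests on few of the reads. Histones did not follow, with 5 of 25 higher and 8 lower (relative median 0.65, percentile 90.28), among them histone H2A, 9.31-fold higher (4.23 to 24.2). Without histone-modifying enzymes and other off-target matches 5 of 17 were higher and 7 lower (relative median 0.24, percentile 62.9), and the raw median turned from 0.16 to −0.25.

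Most heat shock proteins and chaperones were also lower in pupae, with 74 of 120 members lower and 11 higher (relative median −1.002, percentile 0). The small heat shock protein had 2581 reads in prepupae and 75 in pupae, 29.0-fold lower (23.1 to 37.0). Heat shock protein 70 was 8.15-fold lower (6.93 to 9.64), and a mitochondrial-type chaperonin of 60 kDa went from 163 reads to 1, 138-fold lower (24.3 to 5464).

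Hormone genes differed between pathways. The 5 ecdysone receptor unigenes held 121 and 103 reads in sum (1.01-fold, 0.768 to 1.32), and the receptor's partner ultraspiracle had 51 and 43 (0.999-fold, 0.650 to 1.53). E75, an early ecdysone response gene, had 58 and 76 reads (1.55-fold, 1.09 to 2.23). Broad had only 6 and 9 reads (1.78-fold, 0.565 to 6.07), with an interval that includes no change. The 4 unigenes matching FTZ-F1 by name held 113 and 115 together (1.21-fold, 0.922 to 1.58), a sum that may mix genes. Those named FTZ-F1 beta had 44 and 26 and 23 and 28 reads. Those named FTZ-F1 without beta had 27 and 29 and 19 and 32. None of these values passed the rule of size on the deposited scale. There the log2 ratio was 0.63 for E75, 0.74 for broad and 0.92 for the FTZ-F1 unigene with 19 and 32 reads. Centring, which subtracts −0.49 from each log2 ratio, would take these past the rule as higher in pupae. The most abundant ecdysone receptor unigene (0.24) and ultraspiracle (−0.00082) would stay short of it. The receptor of ecdysis-triggering hormone, which starts the moulting behaviour, was 5.33-fold higher (2.96 to 10.3). The ecdysone list as a whole had 5 of 59 members higher and 5 lower (relative median 0.59, percentile 97.91), and percentile 96.8 under TMM scaling. Without off-target members 5 of 33 were higher and 1 lower, and after centring 16 of the 59 were higher and 2 lower. Its raw median was 0.09 and its summed reads were 0.935-fold (0.880 to 0.995), again opposite in sign. Juvenile hormone genes had 49 of 73 members lower and 9 higher (relative median −1.26, percentile 0), although their summed reads were 1.19-fold higher (1.14 to 1.24). The 4 unigenes of epoxide hydrolase, which degrades the hormone, were 2.48-fold lower in sum (1.94 to 3.20) and not uniform. One was 9.84-fold lower (4.99 to 22.1), while another had 24 and 27 reads. Of 48 unigenes matching juvenile hormone esterase, another degrading enzyme, 36 were lower and 6 higher; 1 of the 48 was an esterase binding protein. Their summed reads were 2377 and 2904, 1.45-fold higher (1.37 to 1.53), opposite in sign to most of the calls. Of the higher ones, one went from 1 to 1531 reads (1815-fold, 325 to 71727) and another from 0 to 582. No unigene matched Kruppel homolog 1 or hexamerin by name.

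**Figure D3:**
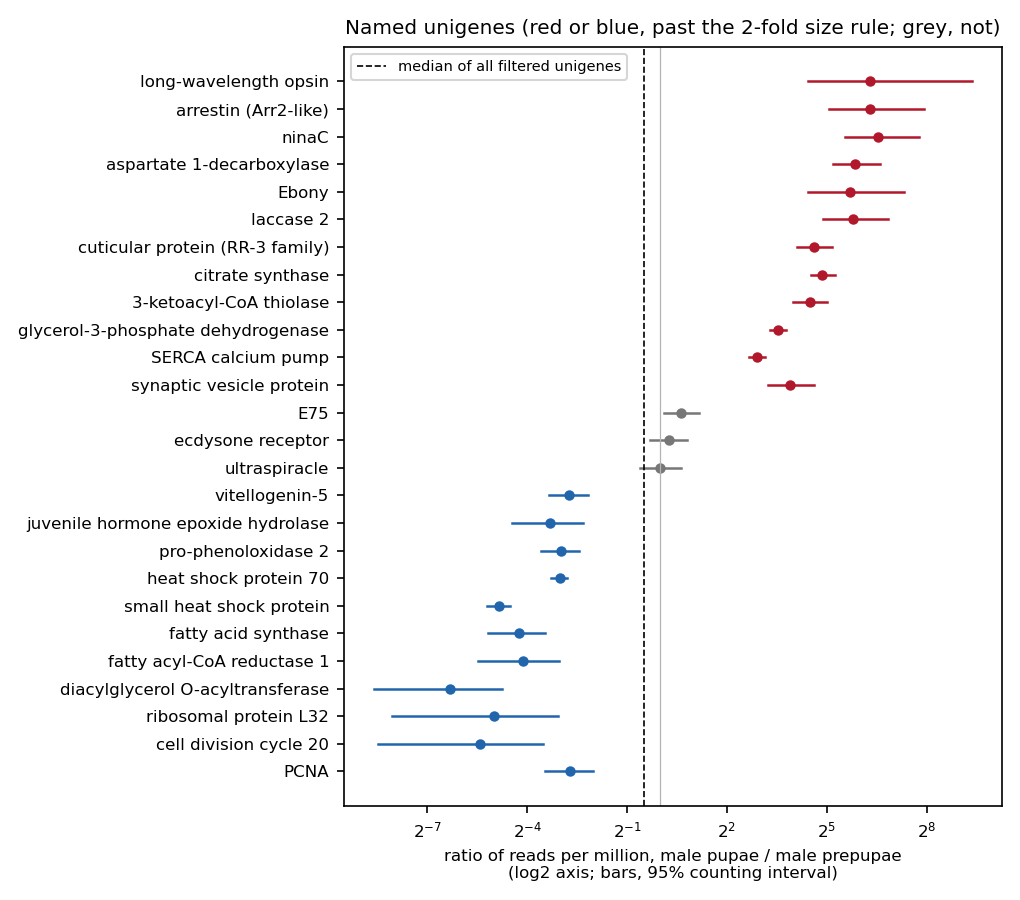
Ratio of scaled reads (RPM) in male pupae to male prepupae for 26 named unigenes (log2 axis), with 95% counting intervals as bars and the median of all filtered unigenes as a dashed line. The opsin lies at 78.8 and the ecdysone receptor and ultraspiracle lie near 1.

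Most yolk and ovary genes were lower in pupae. Vitellogenin-5 had 236 and 30 reads, 6.64-fold lower (4.53 to 10.1), and the 4 vitellogenin unigenes together 699 and 131, 4.50-fold lower (3.73 to 5.47). All 15 unigenes of the storage and yolk list were lower (relative median −1.69, percentile 0.01), but 7 of them were vitellogenin receptor fragments with 31 and 1 reads. Without the receptor and chorion peroxidases 4 members were left, all lower, and the list was no longer extreme (percentile 2.86). Of 28 matches to egg and ovary keywords, 23 were lower and none higher (relative median −1.39, percentile 0.03). Without off-target matches 20 of 22 were lower, and some that stayed, such as the methyltransferase eggless, are not specific to females. Sex determination genes were few, with 3 of 7 lower and none higher (relative median −0.48, percentile 24.4). Sex-lethal was 5.52-fold lower (2.91 to 11.6), fruitless had 32 reads in each library, and 2 unigenes with doublesex in their match held 76 and 24 reads in sum, 2.67-fold lower (1.67 to 4.42). Of these, one named male specific had 42 and 22 reads (1.61-fold lower, 0.940 to 2.83) and a doublesex-Mab related one 34 and 2.

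The list of other transcription factor families, which shares members with the homeobox list, had 157 of 373 members lower and 24 higher (relative median −0.29, percentile 0.24). Against random lists of annotated unigenes, which leaned lower as a whole, the percentile was 29.3. A C/EBP beta homolog was 101-fold higher (34.1 to 492) from 3 reads to 255, and a YY2-like factor 54.0-fold lower (9.35 to 2165) from 64 reads to 1. Homeobox genes had 11 of 79 higher and 25 lower (relative median 0.25, percentile 78.13), with LIM homeobox factor 1 beta 19.0-fold lower (10.4 to 38.6) and onecut 3.06-fold higher (1.77 to 5.50). Wing and appendage patterning genes had 14 of 111 higher and 51 lower (relative median −0.20, percentile 12.61). Without off-target members 7 of 98 were higher and 48 lower, at percentile 1.70, or 16.2 against annotated unigenes (56.6 for the full list). Vestigial, a selector of wing identity, was 3.46-fold higher (2.15 to 5.75), while a BAMBI-like inhibitor of BMP signals was 3.04-fold lower (2.17 to 4.33) and a fat-like cadherin 3.31-fold lower (1.82 to 6.45).

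Detoxifying enzymes had 169 of 333 members lower and 75 higher (relative median −0.53, percentile 0), with summed reads 1.16-fold higher (1.13 to 1.19). A glucosyl/glucuronosyl transferase went from 2 to 605 reads (359-fold higher, 98.8 to 2968), a cytochrome P450 from 2 to 342 (203-fold, 55.7 to 1680.5), and glutathione S-transferase D1 from 105 to 2 (44.3-fold lower, 11.96 to 371). Proteases and their inhibitors had 140 of 292 lower and 46 higher (relative median −0.46, percentile 0), but percentile 91.6 among the 81 of at least 500 bases. Serine protease inhibitor 13 was 46.6-fold lower (17.9 to 173), and another serine protease inhibitor went from 1 to 315 reads (373-fold higher, 66.5 to 14794). Immune genes had 8 of 54 higher and 18 lower (relative median 0.01, percentile 38.16), among them an i-type lysozyme 6.14-fold lower (3.74 to 10.7). Apoptosis and autophagy genes had 4 of 92 higher and 33 lower (relative median −0.15, percentile 16.4).

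Sperm and cilium genes had 52 of 107 members lower and 10 higher (relative median −0.49, percentile 1.14), with percentile 10.4 against annotated unigenes. Without off-target members such as spermidine synthase 28 of 76 were lower and 10 higher, at percentile 11.1 (34.96 against annotated unigenes). Mobile elements had 126 of 648 higher and 183 lower (relative median 0.27, percentile 99.21). Their raw median was −0.22 as deposited, 0.15 with TMM scaling and 0.27 after centring, so the direction turns with the scaling, and summed reads were 1.10-fold higher (1.06 to 1.14). The keywords for fungal and bacterial best matches caught 8 unigenes (1 higher, 5 lower, percentile 5.02) and 3 (none higher, 1 lower, percentile 54.49), all of them through words within protein names, and none matched a plant.

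Among the remaining unigenes with the largest changes were several of less settled role. A unigene named soldier-specific protein-1 had 3 and 688 reads (272-fold higher, 92.6 to 1321), one named harpin 1 and 394 (467-fold, 83.3 to 18493), and a kynurenine aminotransferase, which acts in tryptophan breakdown, 4 and 435 (129-fold, 49.99 to 475). On the lower side, gamma-glutamyl hydrolase had 200 and 1 reads (169-fold lower, 29.9 to 6697), alpha-esterase 41 had 260 and 2 (110-fold, 30.1 to 910), and an AMP-dependent CoA ligase 145 and 1 (122-fold, 21.6 to 4864).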

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

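The alternatives of scaling without the 100 most abundant unigenes, an annotated background and lists without off-target members were chosen after the results had been seen. No paired analysis was possible because each stage had 1 library, and no library could be left out in turn. Against 26264 unigenes higher and 44893 lower, a pseudocount of 5 gave 14515 and 25897, a mean of at least 5 gave 14049 and 25063, 1 unigene per annotation text 3941 and 11119, at least 500 bases 2383 and 5649, the 4-fold threshold 12929 and 21332, and counting intervals beyond 2-fold 5230 and 8367. Stricter thresholds and fewer unigenes lower these counts by construction; lower calls outnumbered higher ones in all of these settings. Centring gave 34136 and 35695, TMM 32178 and 38060. The median of mobile elements reversed to 0.27 after centring and 0.15 under TMM, which shift all ratios upwards. Medians of chitin (0.29 and 0.18), homeobox genes (0.25 and 0.10) and the bacterial keywords (0.27 and 0.18) changed sign in both too, and after centring those of lipid breakdown (0.05), glycolysis (0.02) and immunity (0.0047). Respiration turned to −0.14 with no filter; without off-target members lipid breakdown turned to 0.0048 and histones to −0.25. Among unigenes of at least 500 bases the medians for eyes and for odour and taste reversed to −0.15 and −2.17; only 2 odour and taste unigenes were left, and the cause for eyes was not tested. There the medians also changed sign for tanning (1.22), chitin (0.38), homeobox genes (0.12) and respiration (−0.28). Of 18 lists with an extreme percentile, 10 were extreme on the same side under every alternative run. The other 8 lost it in at least 1 setting: ecdysone (96.8 under TMM), storage and yolk (2.86 without off-target members), muscle (93.8 at 500 bases), other transcription factors (29.3 on the annotated background), sperm and cilia (10.4 there), eyes (94.3 at 500 bases), odour and taste (8.31 at 500 bases) and proteases (91.6 at 500 bases). Lists that became extreme were tanning (99.7), homeobox genes (98.7), chitin (98.4), histones (98.6, with 5 unigenes) and the fungal keywords (0.155, with 1) at 500 bases, wings (1.70, but 16.2 with an annotated background as well) without off-target members, and chitin (98.5) and histones (98.8) on the annotated background. With 1 unigene per annotation text, chitin (98.8) and histones (98.7) did too. That setting left the members and the median of every list unchanged, as for wax and lipid synthesis (130 unigenes, −2.71). For the lists it thus amounts to an annotated background and is no separate check. It did not merge the several unigenes of 1 protein, so the effect of such fragments on the lists was not tested. Muscle lost its extreme percentile at 500 bases although its relative median did not fall there (1.38, against 1.21 in the main setting). Of 148 named unigenes past the rule of size, 146 stayed past it in the same direction under the 4 alternatives run on them. Most of the 148 had been named for a large change, so this outcome was largely set by their selection. The exceptions were a succinate dehydrogenase (0.97 at a pseudocount of 5) and prospero (−0.89 after centring). The share of reads held by the top 10 and top 100 unigenes was 0.469% and 2.22% in prepupae and 1.48% and 6.89% in pupae by counts, and was higher by RPKM. The correlation between libraries was 0.41 with a mean of at least 5. Depth did not account for the larger number of unigenes seen in prepupae, since 102952 were left after thinning to the pupal depth, against 94524 in pupae.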

Other observations

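All tests in this part were chosen after the results had been seen.

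The median ratio over all filtered unigenes lay below 1. On the log2 scale it was −0.49, and −0.43 once library totals left out the 100 most abundant unigenes of either library. The size of this move was set by the reads that stayed, 98.0% in prepupae and 93.6% in pupae. These unigenes therefore account for little of the shift. Whether a larger set of abundant pupal transcripts took reads from the rest was not tested. The median was −0.49 among unigenes with at least 50 reads, which argues against low counts, and medians of 8 length classes differed by at most 0.0953, which argues against length. Annotated unigenes with at least 20 reads had a lower median (−0.71) than those without annotation (−0.38). A broader change in RNA composition and a difference in library making stay open, since each stage has 1 library.

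Most heat shock and chaperone unigenes were lower in pupae. The HSP70 family, cognates included, and the small heat shock unigenes alone did not carry the list. The 85 other members had 55 lower and 6 higher, at percentile 0. This split by name does not separate stress-induced from constant chaperones. Stress or handling of the 1 prepupal sample could be a cause and cannot be told apart from a difference of stage, because there was 1 sample per stage.

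Prophenoloxidase unigenes were lower in pupae while some other tanning enzymes, 19 of 40 unigenes, were higher and 13 lower. Fewer haemocytes of all kinds would lower all haemocyte transcripts alike, but hemolectin reads summed to 51 in prepupae and 496 in pupae, 11.5-fold higher (8.63 to 15.7). Reads moved between the 16 named prophenoloxidase copies would leave their sum about equal, but it was 0.0867-fold (0.0670 to 0.111). As none of the 16 was higher, this sum restates those calls. It covers uniquely assigned reads of named copies only. The other haemocyte markers listed for this test were mixed: hemocytin had 2 and 4 reads, croquemort 623 and 603 (3 of 4 unigenes lower, median −2.01), draper 314 and 267, serpent and lozenge together 52 and 13 (3 of 3 lower), peroxidasin 739 and 108 (9 of 11 lower), and nimrod matched no unigene. The lower markers go with a loss of some haemocytes, and hemolectin argues only against a loss of all kinds alike. A change in the haemocytes that make prophenoloxidase may remain as an explanation, as may regulation of the genes themselves; neither was tested.

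Gene Ontology terms were read without preset choices. Of 276 process terms, 78 were extreme on the higher side and 46 on the lower, by the percentiles used for lists; of 134 function terms 41 and 34; of 79 component terms 20 and 22. Terms share unigenes, so these counts are not independent. Medians of terms are raw, not relative to the overall shift. Secondary active transmembrane transporters had 33 of 49 unigenes higher and 3 lower (median 2.08), and rhodopsin mediated phototransduction 18 of 26 higher and 1 lower (median 1.80). Aminoacyl-tRNA ligases had 106 of 137 lower and none higher (median −1.67), spliceosomal complex members 136 of 191 lower and none higher (median −1.38), and DNA repair 69 of 84 lower and 1 higher (median −1.66).

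The protein families in this paragraph lie outside the preset lists, were picked for their values and were set against no background of other unigenes. The 2 phosphoenolpyruvate carboxykinase unigenes, of the entry step of glucose synthesis, summed to 69 reads in prepupae and 1905 in pupae (32.7-fold higher, 25.7 to 42.2). Glycogen synthase had 209 and 20 reads (8.82-fold lower, 5.56 to 14.7). The 20 monocarboxylate transporter unigenes, 8 higher, none lower and 12 neither (median 0.16), summed to 645 and 2340 reads (4.30-fold higher, 3.94 to 4.70). Splicing factors had 56 of 83 unigenes lower and proteasome subunits 31 of 53, with none higher in either family.

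Transcripts that are abundant in most animal RNA libraries were scarce in both libraries. Cytochrome c oxidase subunits 1 to 3 matched 3 unigenes with 2 reads in prepupae and 1 in pupae, and elongation factor 1 alpha held 138 and 46 reads. No test here tells why. If such reads had been left out of the counts, or the libraries evened out before sequencing, the folds, the read shares and the decrease of ribosomal proteins would describe the remaining reads and not the RNA of the animals.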
